A study of Mus musculus with 2 samples.

How the data were processed

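Adenoma organoids of 2 cultures, 1 without and 1 with RSPO1-Fc, were each measured as 1 droplet library with 3′ counting of UMIs. Groups were taken from the treatment label. Per the labels' protocols the 10x Chromium v2 chemistry was used with a target of 5000 cells per library, mean reads per cell were 58414 (control) and 131291 (RSPO1-Fc), and reads were aligned to mm10. The submitters' processing notes name Cell Ranger 2.1.1 and Seurat 3.1.1. The control matrix, however, names Cell Ranger 3.1.0 per the file headers, lists 31053 genes and 6794880 barcodes, and so differs from the RSPO1-Fc matrix with 27998 genes, 737280 barcodes and no software in its header. The deposited values are raw UMI counts per gene and barcode, not normalized and not filtered for cells. A barcode list of the control's length belongs to the v3 chemistry, not to the v2 of the labels, so a difference in chemistry cannot be told apart from RSPO1-Fc. A combined Seurat object named in the labels was not used here.

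The design text states 5000 cells in each sample. Of the barcodes in the files, those with a total of at least 0.1 of the 99th percentile of the 5000 highest totals were called cells, which set limits of 9809.2 UMIs (control) and 5959.3 UMIs (RSPO1-Fc) and called 2269 and 2767. No filter of the study is given in the sources used here. Cells needed at least 500 genes, which removed 0, and at most 20% mitochondrial UMIs, which removed 18 and 22. Doublets were scored with scrublet in scanpy 1.11.5, and the highest 0.8% per 1000 barcodes were removed, which took 41 and 60 cells (1.8% and 2.2%). The tool's own threshold would have marked 28 and 2. The retained 2210 and 2685 cells held 77.8% and 76.1% of the UMIs, with medians of 5157 and 4753 genes and 5.89% and 3.39% mitochondrial UMIs.

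The tables were joined on 27514 shared Ensembl identifiers, of which 27480 are in the GENCODE M21 annotation of GRCm38 used for coordinates and 1027 carry different symbols. Genes in only one table (3539 and 484) were left out. Of these, 3531 and 242 are in that annotation, and only they could be checked for overlap. They overlap 162 and 2 shared genes on the same strand (bedtools 2.31.1), and such shared genes are named as uncertain. UMIs were summed over cells per library, scaled to CPM over shared genes and compared as log2((RSPO1-Fc + 1)/(control + 1)), with a pseudocount of 1 CPM. This understates ratios of low genes. Fold values come from CPM without the pseudocount. Intervals are exact Poisson intervals for sums, conditional Clopper-Pearson for ratios and Clopper-Pearson for shares. Where a limit is given for a share of 0, it is the one that 3 counts would set. A fold against 0 UMIs was set against a floor of 3 counts in the library and is given as "at least". Cells are not replicates, so no p-value was computed.

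Genes counted as different had at least 20 CPM in either library and a 2-fold difference. The 20 gene lists and 16 cell type lists, the filters, the alternatives set in advance and the rule for naming genes were fixed before the data were examined. That rule took the 10 highest and 10 lowest ratios without mitochondrial, ribosomal protein and unnamed gene models, up to 4 members per list with the largest ratios, and always Lgr5, Axin2, Rnf43, Znrf3, Ascl2, Olfm4 and Mki67. Within a class it took the 5 highest and 5 lowest. Some genes chosen by this rule are not reported here. A list median needed 4 members at 5 CPM or more and is placed as a percentile among 10000 random lists matched in 20 expression bins, which describes these libraries only. Its interval resamples members. Some lists share members, so their medians are not independent of each other. Trac and Igkc of the marker lists were not matched in both tables.

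Cells of both libraries were clustered after anchor integration in Seurat 5.3.0 (2000 variable genes, 30 dimensions, resolution 0.8), with the Haswell kernel of the linear algebra library fixed. Cluster borders depend on this kernel. Texts and tests were first drawn up on clusters from a run in which it had not been fixed, were then redone with it fixed, and the clustering was repeated with the Sandybridge and Prescott kernels. A cluster was named from the fixed markers by the largest share of markers at least 2-fold higher than in other cells, with at least 3 and more than 1 in 3 of the class, and stayed unnamed when its 10 leading genes held markers of another class. The markers were fixed in advance, but this naming rule was not: 4 versions were written after the clusters had been seen. Version 1 named a further cluster stem-like and another cycling-like. Versions 1 and 3 left the pericyte-like cluster unnamed, and version 2 also the fibroblast-like one. Unnamed clusters held 73.7% of control and 80.4% of RSPO1-Fc cells. Epithelial clusters are all but the macrophage-like, endothelial-like, fibroblast-like and pericyte-like ones, and may still hold other cells. Without integration 2 further control-only clusters appeared, 34 cells led by S100a9 and 19 led by H2-Ab1, of which 34 and 3 lay in epithelial clusters. A further rule on single cells, at least 5 UMIs of non-epithelial markers and more of them than of Epcam, Krt8, Krt18 and Krt19, found 31 control and 0 RSPO1-Fc cells in epithelial clusters. Leaving out both, 65 cells, an alternative added after seeing the data, gave a Wnt target median of −1.68. The share of cycling-like cells was not compared. Shares of cells with a UMI were taken after thinning to 3000 UMIs, which left out 0 cells.

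TMM factors came from edgeR 4.0.16 in R 4.3.3. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered the gene, mitochondrial and UMI limits, doublets, thinning, scaling, per-cell means, subtraction of free RNA, pseudocounts, expression floors and clustering settings. On simulated counts for 27514 genes of the RSPO1-Fc against control comparison, the 2-fold rule called 0% of 71 genes changed 1.5-fold, 100% of 66 changed 3-fold and 100% of 63 changed 6-fold, and 0 unchanged genes. Ratio intervals held the simulated value for 95.4% of 12909 genes, and 3.4% of 500 random lists fell outside the central 95%. Both simulated libraries were drawn with counting error only from a shared profile. They therefore say nothing on differences between animals, cultures or library preparations.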

Results

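Single-cell 3′ RNA sequencing was performed on organoids grown from intestinal adenomas of C57BL/6 mice that carry the Min allele of Apc, a tumour suppressor that restrains Wnt/β-catenin signalling. The mice were 17 weeks old. One culture received RSPO1-Fc, a fusion of the Wnt agonist R-spondin 1 to an antibody Fc part, and the other did not. The dose was 10 μg/ml per the treatment protocol, while another label of the same sample gives this number in milligrams. Each group held 1 library, so no difference has a replicate check and no test between the groups was possible. Unique molecular identifiers (UMIs) totalled 91675581 in the control library and 89437327 in the RSPO1-Fc library. After filtering, 2210 control cells with a median of 24730 UMIs and 2685 RSPO1-Fc cells with a median of 23361 UMIs were retained. Intervals are 95% intervals and cover counting error only. Those of levels and folds do not cover variation between cells.

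The comparison asked how gene expression and cell makeup of adenoma organoids differ with RSPO1-Fc. Most genes activated by Wnt/β-catenin were lower in the RSPO1-Fc library, among them the intestinal stem cell receptor Lgr5 (6.09-fold, interval 5.66 to 6.55) and the feedback inhibitors Axin2 (3.04-fold, 2.96 to 3.12) and Wif1 (60.6-fold, 56.9 to 64.7). Most measured members of the cell cycle, cholesterol synthesis, hypoxia and glycolysis, and enterocyte lists were higher. Macrophage-like, endothelial-like, fibroblast-like and pericyte-like cells made up 16.2% of the control cells (358 of 2210, 14.7 to 17.8) and 0.0372% of the RSPO1-Fc cells (1 of 2685, 0.000943 to 0.207). Some genes that depend on gut segment or sex also differed between the libraries, and Xist, the RNA that silences an X chromosome in female cells, had 103624 UMIs in the control library and 3 in the RSPO1-Fc library (32993-fold lower, 11289 to 159988).

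Among the non-epithelial cells, the macrophage-like cluster held 175 control cells, or 7.92% (6.83 to 9.12), and 1 RSPO1-Fc cell. That cell carried the epithelial adhesion gene Epcam at 2307 CPM (counts scaled to a common library total), against 43.5 CPM in the macrophage-like control cells. The endothelial-like, fibroblast-like and smooth muscle or pericyte-like clusters held 74, 72 and 37 control cells and 0 of 2685 RSPO1-Fc cells, which allows a share of up to 0.112% for each. The marker lists followed. The median log2 ratio of RSPO1-Fc over control was −5.96 for 6 macrophage markers (−7.65 with the 2 members at 0 UMIs set to their bound), −6.35 for 6 fibroblast markers, −3.10 for 5 smooth muscle or pericyte markers and −3.63 for 5 endothelial markers. Tuft-like cells, a chemosensory epithelial type, numbered 15 in the control library (0.679%, 0.380 to 1.12) and 4 in the RSPO1-Fc library (0.149%, 0.0406 to 0.381). A cluster with 3 stem markers higher, kept out of the stem class by a threshold set after the clusters had been seen, held 14.2% of control cells (12.8 to 15.7) and 2.5% of RSPO1-Fc cells (1.94 to 3.16). Its 10 leading genes, headed by Pnliprp2 and Ceacam10, held no stem marker. Without integration, a cluster also led by Pnliprp2 held 353 control and 0 RSPO1-Fc cells and had under 3 markers of any class higher. These shares are therefore not read as a difference in stem cells. A cluster led by defensin and enteroendocrine genes, unnamed because it mixed markers of 2 classes, held 0.136% (3 cells, 0.0280 to 0.396) and 1.45% (39 cells, 1.03 to 1.98).

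**Figure D1:**
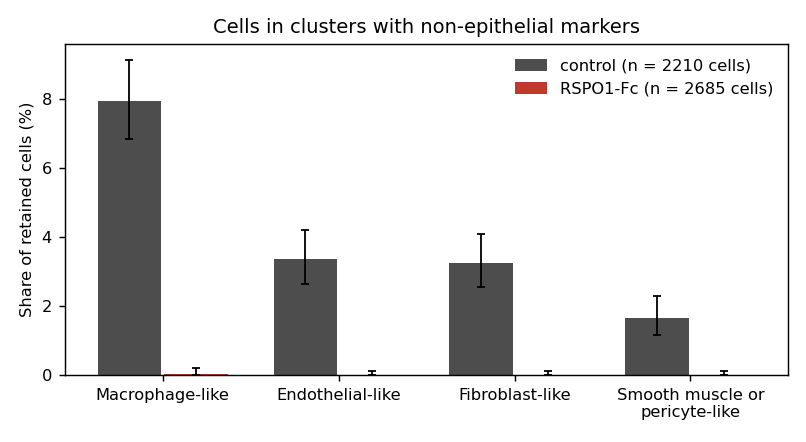
Share of retained cells (%) in clusters with non-epithelial markers, for 2210 control cells and 2685 RSPO1-Fc cells, 1 library each. Bars are shares and lines exact 95% binomial intervals; the macrophage-like share was 7.92% in the control library and 0.0372% in the RSPO1-Fc library.

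Wnt target genes were lower as a group in the RSPO1-Fc library. Of 20 measured members 17 were lower and 12 at least 2-fold lower. Cd44, counted among the 17, stood at 86.7 CPM in the control and 86.2 CPM in the RSPO1-Fc library (1.01-fold lower, 0.971 to 1.04). The median log2 ratio of the list was −1.53 (−2.43 to −0.40 from resampling the members). It lay at percentile 0 among 10000 random lists of equal size and expression, which centred at −0.14. With the 4 named non-epithelial clusters left out, a choice made after seeing the data, the median was −1.65, and −1.68 without 65 further control cells of 2 clusters led by immune genes or with non-epithelial marker UMIs. Prox1, a transcription factor switched on in intestinal adenomas, was 498 CPM in the control and 51.6 CPM in the RSPO1-Fc library (9.65-fold lower, 9.32 to 9.99). Lef1, which binds β-catenin at target genes, was 10.0-fold lower (9.10 to 11), Nkd1 was 767 and 95.9 CPM, and Notum, an enzyme that inactivates Wnt ligands, was 252 and 48.4 CPM. Ascl2, a stem cell transcription factor, was instead 25.4 CPM in the control and 36.8 CPM in the RSPO1-Fc library (1.45-fold higher, 1.36 to 1.54), and Myc and Ephb2 were also higher, with log2 ratios of 0.29 and 0.61. Nkd1, Notum, Myc and Ephb2 were picked after their values were seen.

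**Figure D2:**
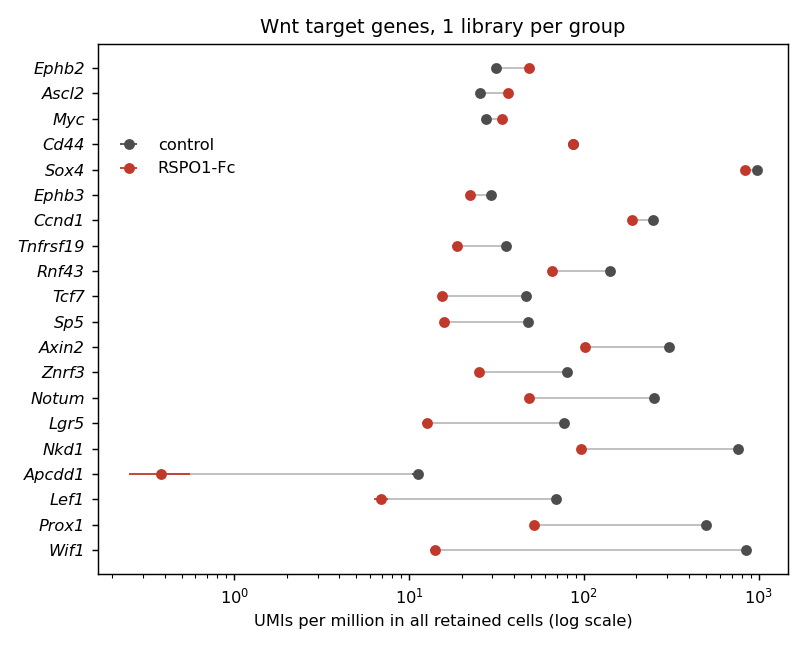
CPM (log axis) of the 20 Wnt target genes in all retained cells of the control and RSPO1-Fc libraries, 1 library each. Points are levels, coloured lines exact 95% Poisson intervals and grey lines join the libraries. In the RSPO1-Fc library 17 genes were lower, Cd44 among them by only 1.01-fold. Wif1 was 849 in the control and 14.0 in the RSPO1-Fc library.

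Secreted and membrane Wnt antagonists were lower in all 9 measured members, 8 of them at least 2-fold, with a median log2 ratio of −2.71 (−3.54 to −1.09; percentile 0). Wif1, Notum, Apcdd1, Rnf43 and Znrf3 of this list are also in the Wnt target list, so the medians are not separate results. Dkk2 was 12.5-fold lower (11.6 to 13.4), Dkk3 11.5-fold (10.4 to 12.6) and Apcdd1 29.3-fold (19.9 to 45.2). Among 9 R-spondin and Wnt receptor genes 6 were lower, with a median of −1.09 (−2.51 to 1.15; percentile 1.71), which was −0.44 after thinning to 3000 UMIs. Lgr5, Rnf43 and Znrf3 of these genes are Wnt target list members too. Rnf43 and Znrf3, the ubiquitin ligases that R-spondins clear from the cell surface, were 2.14-fold (2.07 to 2.22) and 3.18-fold (3.01 to 3.35) lower, and Lgr6 was 176-fold lower (59.9 to 856). The R-spondin receptor Lgr4 was 2.54-fold higher (2.43 to 2.65).

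Stem markers had a median log2 ratio of −1.40 (−2.43 to 0.52; percentile 0.03), and 6 of 8 were lower. Lgr5, Ascl2 and Axin2 of these markers are shared with the Wnt target list. Smoc2 was 3.28-fold lower (3.15 to 3.4) and Gkn3 6.77-fold lower (5.87 to 7.84). With every cell thinned to 3000 UMIs, Lgr5 was detected in 14.8% of control cells (13.3 to 16.3) and 3.76% of RSPO1-Fc cells (3.07 to 4.55). In macrophage-like control cells, which should lack it, the share was 0.571%; these cells had a median of 14092 UMIs. The RSPO1-Fc library held no such class, so for every gene the share due to free RNA is unknown there. Without thinning the Lgr5 shares were 45.0% and 21.9%. Olfm4, another stem cell gene, had 4 UMIs in the control and 0 in the RSPO1-Fc library and was seen in 0 thinned cells of either, which allows shares with a UMI of up to 0.136% and 0.112% at that depth. Without thinning it was seen in 3 of 2210 control cells (0.136%, 0.0280 to 0.396) and 0 of 2685 RSPO1-Fc cells, which allows up to 0.112%.

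Some genes with a known place along the gut or on a sex chromosome differed by large factors. They were singled out after the extremes had been seen. Hoxa9, Hoxa10 and Hoxb13, homeobox genes of the posterior body, stood at 140, 107 and 96.4 CPM in the control library and had 1, 1 and 0 UMIs in the RSPO1-Fc library (9487-fold lower, 1702 to 374744; 7257-fold, 1302 to 286689; at least 2184-fold). Gata4, a transcription factor of the proximal small intestine, was 3145-fold higher (564 to 124261), from 1 UMI in the control. The Y-linked genes Eif2s3y and Ddx3y had 0 control UMIs and were at least 1338-fold and 798-fold higher in the RSPO1-Fc library. Uty and Kdm5d had 3 and 2 UMIs in the control and 902 and 628 in the RSPO1-Fc library (315-fold, 107 to 1529, and 329-fold, 90.6 to 2720). Xist lies on chromosome X at 103460366 to 103483254 and Hoxb13 on chromosome 11 at 96194316 to 96197447 of GRCm38, the assembly also called mm10.

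**Figure D3:**
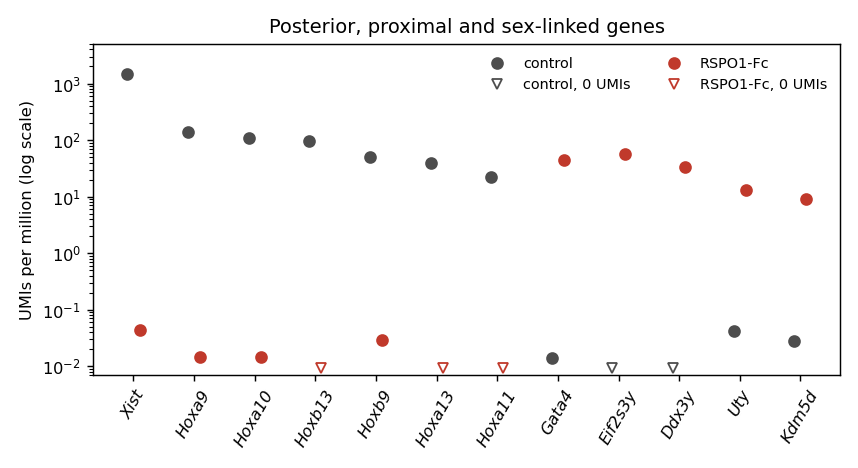
CPM (log axis) of genes tied to gut segment or sex, in all retained cells of 1 control and 1 RSPO1-Fc library. Filled points are levels and open triangles at the bottom mark 0 UMIs, with no meaning in their height; Xist and the Hox genes were higher in the control library, Gata4 and the Y-linked genes in the RSPO1-Fc library.

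BMP target genes were lower in 7 of 8 measured members, with a median log2 ratio of −1.47 (−2.86 to −0.77; percentile 1.09). Id1, an inhibitor of differentiation factors, was 8.14-fold lower (7.93 to 8.36), Bambi 8.17-fold (7.42 to 9.01) and Id4 20.2-fold (13.5 to 31.5), whereas Msx1 was 5.59-fold higher (5.18 to 6.05). TGF-β target genes had a median of −0.71 (−3.01 to 0.21; percentile 1.24), with 9 of 12 lower. In epithelial clusters only, that median was −0.26, and the log2 ratio of Col4a1 went from −3.87 to −0.26 and of Tgfbi from −2.99 to −1.25 (0.69 and −0.72 without these 65 further cells). Smad7, an inhibitor of the TGF-β receptor, had log2 ratios of −3.03 and −3.08. TGF-β pathway components had a median of −0.32 (−0.66 to −0.02; percentile 36.87), which was 0.02 under scaling by trimmed mean of M values (TMM). Tgfb1 was 4.44-fold lower (4.08 to 4.83) in all cells and 1.99-fold lower in epithelial clusters.

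ERK feedback and target genes had a median log2 ratio of −0.43 (−1.51 to 0.36; percentile 17.08), with 9 of 15 lower. Etv5 was 13.8-fold lower (12.7 to 15.1), Spry4 18.9-fold (13.2 to 28.1; 12.4-fold in epithelial clusters) and Dusp6 3.4-fold (3.18 to 3.65). YAP target genes were evenly split in all cells (5 higher and 5 lower, median −0.03, −0.52 to 1.36; percentile 76.12) and had a median of 0.33 under TMM. In epithelial clusters 8 were higher and 2 lower, with a median of 0.66 (0.11 to 1.34; percentile 99.93). Areg, a ligand of the EGF receptor, was 5.29-fold higher (5.06 to 5.53). Crim1 was 2.10-fold lower (1.91 to 2.30) in all cells, with a log2 ratio of 0.61 in epithelial clusters. Notch pathway genes had a median of −0.11 (−2.30 to 0.48; percentile 77.78), 0.24 under TMM and 0.20 in epithelial clusters. Hey1 was 22.3-fold lower (13.6 to 39.5) and Notch1 3.96-fold lower (3.67 to 4.27), while Notch2 was 2.13-fold higher (1.94 to 2.33).

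Enterocyte markers were higher in 6 of 7 measured members, with a median log2 ratio of 2.93 (0.28 to 3.35; percentile 100). Krt20, a keratin of mature epithelium, was 19.3-fold higher (17.0 to 22.1). The fatty acid binding protein genes Fabp2 and Fabp1 were 15.2-fold (12.7 to 18.2) and 125-fold higher (48.5 to 461), but had log2 ratios of −0.94 and −0.06 after subtraction of the profile of barcodes with over 100 and up to 500 UMIs, an alternative added after seeing the data. It took free RNA as 12.27% of control and 26.85% of RSPO1-Fc UMIs and gave a list median of 1.76. Fabp1 was seen in 0 of 2210 thinned control cells, which allows a share with a UMI of up to 0.136% at that depth, and in 2.12% of RSPO1-Fc cells (1.61 to 2.74), and without thinning in 0.136% (0.0280 to 0.396) and 8.98% (7.92 to 10.1). No order is read from these shares.

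Goblet markers had a median of −1.90 (−4.09 to 1.95; percentile 0.18), with 3 of 5 lower. Without integration, where most clusters held 1 library only, a goblet-like cluster held 206 control and 0 RSPO1-Fc cells and a Paneth-like one 2 and 48, so neither share is read as a difference. The mucin gene Muc2 was 52.3-fold lower (36.7 to 77.2), from 1697 UMIs in 68 control cells and 31 UMIs in 21 RSPO1-Fc cells. It was seen in 0.769% (0.449 to 1.23) of thinned control and 0.0745% (0.00902 to 0.269) of thinned RSPO1-Fc cells. No order is read from these shares, because 0 of 175 macrophage-like control cells allow a background of up to 1.71%. Spink4 was 17.7-fold lower (16.6 to 19.0) and Agr2 3.80-fold lower (3.65 to 3.96), and Tff3 was 3.94-fold higher (3.78 to 4.11). Spink4 and Agr2 were also present in control cycling-like cells, at 211 and 192 CPM against 241 and 162 CPM in all control cells. Their folds are therefore not read as a difference in goblet cells. Paneth markers had a median of 0.03 (−0.70 to 1.52; percentile 61.6) and −0.09 in epithelial clusters. The defensin Defa22 was 10.9-fold higher (10.3 to 11.4) and the lectin Itln1 2.11-fold lower (2.03 to 2.19). Defensin genes are near-identical copies, so their single values are uncertain. Lyz1 was seen in 9.50% (8.31 to 10.8) of thinned control and 10.9% (9.79 to 12.2) of RSPO1-Fc cells, but also in 76.0% of macrophage-like cells. In epithelial clusters the shares were 4.16% (3.29 to 5.17) and 11% (9.8 to 12.2), but the CPM was 1.29-fold lower there (1.25 to 1.33) and 1.5-fold lower (1.45 to 1.55) in all cells, so no order is read.

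Enteroendocrine and tuft lists had 3 measured members each, too few for a median. Among enteroendocrine genes the hormone gene Sct was 16.6-fold higher (14.7 to 18.7), Chgb 2.99-fold (2.43 to 3.71) and Pyy 1.87-fold (1.77 to 1.96), the last lower after subtraction of free RNA from barcodes with over 100 and up to 500 UMIs (log2 −0.27). Chga was seen in 0.226% (0.0735 to 0.527) of thinned control and 0.857% (0.544 to 1.28) of RSPO1-Fc cells. Dclk1, a tuft cell kinase, was seen in 1.36% (0.918 to 1.93) and 0.112% (0.0230 to 0.326). In epithelial clusters its control share was 0.648% (12 of 1852, 0.335 to 1.13) and its fold went from 6.83 to 4.37 (2.97 to 6.6). Chga and Dclk1 were each seen in 0 of 175 macrophage-like control cells, which allows up to 1.71%, so no order is read from their shares. Avil was 14.5-fold lower (13.3 to 15.9). It stood at 106 CPM in control cycling-like cells and 109 CPM in all control cells, so it is not read as a difference in tuft cells. The tuft marker Ptgs1 had a log2 ratio of −1.69 in all cells and 0.08 in epithelial clusters. Fetal or regenerative epithelium markers went both ways, with a median of −0.03 (−3.81 to 1.01; percentile 61.93), 0.36 in epithelial clusters and 0.33 under TMM. Msln was 52.9-fold higher (47.0 to 59.7) and the chaperone gene Clu 2.02-fold higher (1.99 to 2.04), while Ecm1 and Spp1 were 18.2-fold (16.6 to 20) and 155-fold lower (112 to 221), Spp1 65.4-fold (47.3 to 93.1) in epithelial clusters. Clu was seen in 44.4% (42.3 to 46.5) of thinned control and 73.3% (71.6 to 75.0) of RSPO1-Fc cells, against 2.29% of macrophage-like control cells, and no order is read from these shares. Ly6a was 2.13-fold lower (2.06 to 2.21) by CPM, and no order is read from its shares of 14.2% and 14.7%.

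Genes of the S phase were higher in 34 of 38 measured members, with a median log2 ratio of 0.83 (0.61 to 0.95; percentile 100), and genes of G2 and M phase in 42 of 51, with a median of 0.53 (0.29 to 1.02; percentile 100). Ung, which removes uracil from DNA, was 3.21-fold higher (2.93 to 3.52) and Cks2, a subunit of cyclin-dependent kinases, 3.87-fold higher (3.77 to 3.98). The 14 cycling markers had a median of 0.95 (0.28 to 1.25; percentile 100), but all except Ccnb1 are also in the S phase or the G2 and M phase list. Mki67, the gene of the proliferation antigen, was 95.6 CPM in the control and 87.2 CPM in the RSPO1-Fc library, a log2 ratio of −0.13 that was 0.23 under TMM and 0.34 after thinning. It was seen in 10.0% and 19.4% of thinned cells, shares that go against the CPM, so no order is read. The p53 target genes had a median of −0.21 (−0.44 to 0.26; percentile 31.63), which was 0.15 under TMM, and Trp53inp1 was 4.39-fold lower (4.18 to 4.62). Ribosomal protein genes took 21% of control and 28.1% of RSPO1-Fc UMIs, and mitochondrial genes 6.18% and 3.57%.

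Hypoxia and glycolysis genes were higher in 14 of 17 members, with a median of 0.74 (0.38 to 1.25; percentile 100). Eno1, encoding enolase, was 4.50-fold (4.40 to 4.61) and Car9 5.03-fold higher (4.63 to 5.47), but Pgk1 and Vegfa were 3.75-fold (3.63 to 3.88) and 4.50-fold lower (4.13 to 4.92). Cholesterol synthesis genes were higher in 15 of 16 members, with a median of 0.84 (0.49 to 1.15; percentile 100). Unfolded protein response genes had a median of −0.61 (−0.82 to 0.26; percentile 2.64), and Xbp1 was 2.32-fold lower (2.23 to 2.41). Immediate early and dissociation stress genes were lower in 12 of 15 members, with a median of −0.76 (−1.51 to −0.28; percentile 0.07). Jun, Atf3 and Socs3 were 3.75-fold (3.70 to 3.80), 3.81-fold (3.76 to 3.87) and 13.1-fold lower (11.7 to 14.8), while the heat shock gene Hspa1a was 6.84-fold higher (6.38 to 7.34). In epithelial clusters Socs3 was 7.75-fold lower (6.9 to 8.73) and Hspa1a 12.8-fold higher (11.6 to 14.1).

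MHC class II genes were lower in all 6 measured members, with a median log2 ratio of −6.57 (−7.06 to −3.44; percentile 0), beside the 175 macrophage-like control cells that such genes mark. It was −4.26 in epithelial clusters, but 31 control cells there, 17 of them cycling-like, carried non-epithelial markers and held 977 of the 1260 control H2-Aa UMIs. Without these and the 2 further clusters led by immune genes only 1 member was measured, so no difference among epithelial cells is read. Cd74 was 268-fold lower (219 to 330), and 54.1-fold (44.3 to 66.8) in epithelial clusters, where these 31 cells held 2778 of 5073 control UMIs. Interferon response genes were lower in 7 of 9 members, with a median of −1.20 (−2.19 to 0.23; percentile 2.07) and −0.70 in epithelial clusters. Usp18 was 33.7-fold lower (27.8 to 41.3). Antimicrobial and mucosal defence genes had a median of −2.52 (−6.17 to 0.35; percentile 0.01), with 8 of 10 lower. Lcn2, which binds bacterial siderophores, was 1190-fold lower (833 to 1764), S100a9 at least 2121-fold lower and Reg1 73.0-fold higher (57.4 to 94.4). Of 6662 control S100a9 UMIs, 4600 lay in 34 control cells that formed a cluster led by S100a9 and S100a8 only without integration and counted as epithelial here, with Epcam at 2247 CPM. Pan-epithelial genes had a median of 0.50 (−0.31 to 0.64; percentile 92.36), and the keratin gene Krt19 was 2.23-fold higher (2.21 to 2.25). T or NK cell and glia lists had 0 measured members. The B or plasma cell list had 1, Jchain (113-fold lower, 62.9 to 227, but with a log2 ratio of −0.05 in epithelial clusters), and the erythroid list 1, Hbb-bs (16.9-fold lower, 12.2 to 23.9).

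**Figure D4:**
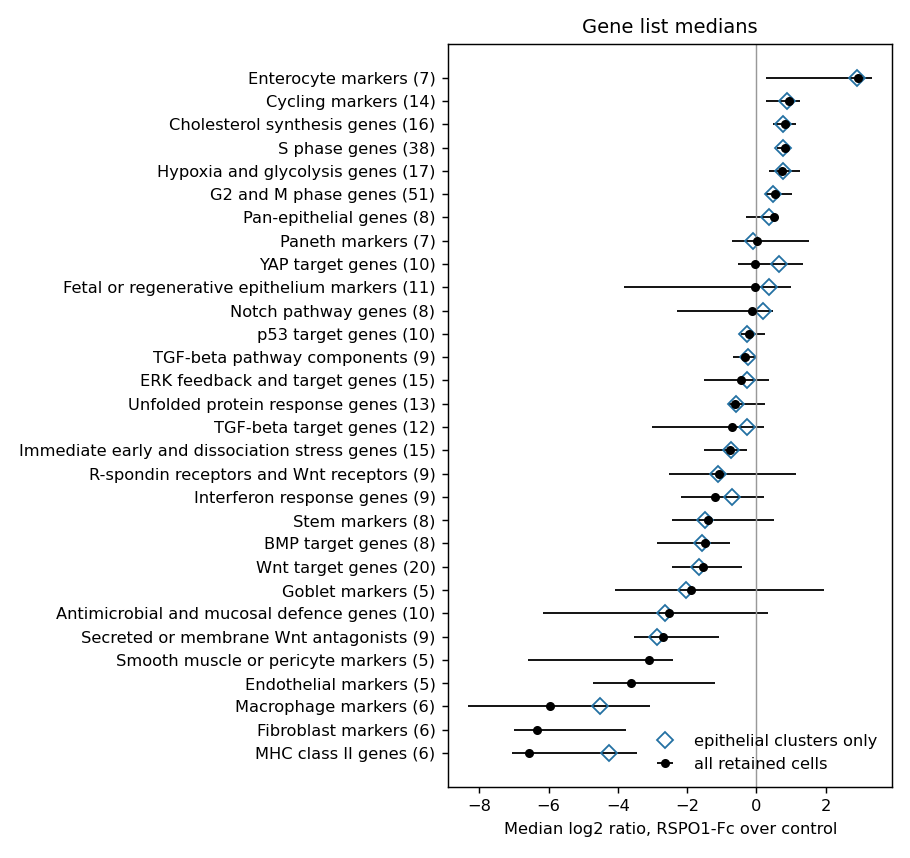
Median log2 ratio, RSPO1-Fc over control, of each gene list, with the number of measured members in brackets and 1 library per group. Black points are all retained cells with 95% intervals from resampling members, open diamonds epithelial clusters only; the Wnt target median was −1.53 and −1.65, while medians near 0 (YAP, Notch, Paneth and fetal lists) changed sign between these cell sets, and the TGF-β component, p53, YAP, Notch and fetal medians under TMM.

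Across 7041 genes with at least 20 CPM in either library, 475 were at least 2-fold higher and 1333 at least 2-fold lower in the RSPO1-Fc library, so 26.3% of these were higher. Under TMM the numbers were 1015 and 810 (55.6% higher), and the median log2 ratio of all genes moved from −0.19 to 0.23. Single ratios are given on the scale of total counts. The Wnt target median was −1.18 under TMM. In epithelial clusters only, 474 genes were higher and 1239 lower, of which 442 and 1151 were shared. The 10 highest ratios were those of Defa32, Defa20, Defa33, Lor, Fdx1l, Eif2s3y, Srp54c, Prap1, Tff2 and Gata4. Lor, a protein of the cornified envelope, was 228-fold higher (181 to 293), Tff2 234-fold (146 to 402) and Prap1 120-fold (90.7 to 162). Fdx1l overlaps, on its strand, a gene that only the control table holds, and Srp54c has near-identical copies, so both values are uncertain. The 10 lowest were Xist, Mgp, Lyz2, Apoe, Lcn2, Alb, Sparc, C1qa, Col3a1 and Cd74. The matrix protein gene Mgp was 3415-fold lower (2255 to 5450) and had a log2 ratio of −9.82 in epithelial clusters, whereas that of Col3a1, a fibroblast collagen, went from −7.37 to −3.18. It was −1.64 for Col3a1 without the 65 further control cells that carried immune or non-epithelial genes.

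Cycling-like cells, the named class with over 100 cells in both libraries, comprised 208 control and 520 RSPO1-Fc cells of 1 cluster, with median UMI counts of 41919 and 28476. Among 6664 genes measured there, 328 were at least 2-fold higher and 970 lower, of which 271 and 813 were shared with all cells. Msln, Prap1, Lor, Fdx1l and Defa20 had the highest ratios and Xist, Mgp, Lyz2, Apoe and Hoxa9 the lowest. Of 3448 control Lyz2 UMIs in this class, 3351 lay in 17 control cells called non-epithelial by marker UMIs. Lyz2 is therefore not read as a difference among cycling epithelial cells. Apoe, also a leading gene of the macrophage-like cluster, was not looked at in this way. Wnt target genes had a median log2 ratio of −0.96 (−2.16 to −0.67; percentile 0) over 19 measured members, with the secreted inhibitor Wif1 at 548 and 2.64 CPM and Axin2 at 257 and 132 CPM. Wnt antagonists had a median of −2.54, BMP targets −0.96, cholesterol synthesis genes 0.88, hypoxia and glycolysis genes 1.10 and enterocyte markers 2.64. Paneth markers had a median of 2.58 (−0.41 to 3.39) among these cells, with 4 higher and 3 lower, and goblet markers −2.13. The higher Paneth markers included defensins such as Defa22 (4 control and 798 RSPO1-Fc UMIs), while Lyz1 and Itln1 were lower. The share due to free RNA is unknown in the RSPO1-Fc library, so no Paneth gene expression by cycling cells is read. Non-epithelial markers took 0.0707% of control and 0.00376% of RSPO1-Fc UMIs in this class. Without the 17 control cells called non-epithelial by marker UMIs, that control share was 0.00534% and the Wnt target median −1.01. The size of the class depended on rounding in the clustering: 2 other numerical kernels gave 313 and 761, or 205 and 511 cells, with Wnt target medians of −1.01 and −0.95.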

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

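Tests of Epcam, free RNA, Hox genes within the cycling-like class, and of the Wnt target list were chosen after the results were seen, and so were the alternatives leaving out non-epithelial cells. Genes held by only one table took 0.17% of UMIs in the control library (led by Pnp at 147.9 CPM) and 0.18% in the RSPO1-Fc library (led by Zfos1 at 303.5 CPM). This signal stands outside the comparisons.

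Non-epithelial cells were 358 of 2210 in the control library and 1 of 2685 in the RSPO1-Fc library. Loss at the UMI limit is argued against, as 0.0% of 1071 RSPO1-Fc barcodes between 1000 UMIs and the limit carried such markers (upper end of the 95% interval 0.344%), against 491 of 1883 (26.1%) in the control, and doublets or free RNA over epithelial cells are argued against by Epcam, which in these control cells was 4.06% of its level in epithelial clusters. Free RNA of such cells in the RSPO1-Fc suspension stays open: their markers were 108.2 times more frequent in barcodes of 1 to 50 UMIs than in retained cells, but only 5.7 times in barcodes of over 100 to 500 UMIs. Barcodes of 1 to 50 UMIs also carried Xist at 35.9 CPM in the RSPO1-Fc library (0.0441 in retained cells) and Ddx3y at 18.5 CPM in the control (0 in retained cells), so RNA of another library could also be the source. A treatment effect, or a difference in how the cultures were established, is untested.

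Some posterior and sex-linked genes differed between the libraries. The non-epithelial cells are argued against, since the median log2 ratio of Hoxa9, Hoxa10 and Hoxb13 among cycling-like cells was −7.01. Reads lost to genes of one annotation are argued against only for genes that could be placed, which overlapped 0.0% of the 8 genes. Of the 484 genes held by the RSPO1-Fc table alone, 242 could be placed. A difference in gut segment is a candidate explanation: all of the 3 other measured Hox genes of groups 9 to 13 (100%) were higher in the control library. These were Hoxa11, Hoxa13 and Hoxb9, which reached the floor of 5 CPM only through the control library. They lie close to Hoxa9, Hoxa10 and Hoxb13 on chromosomes 6 and 11, so they are weak further support. A difference in sex of the animals is also a candidate explanation, although its test missed the bound set beforehand. Kdm5d and Uty together had 1530 UMIs in the RSPO1-Fc library and 5 in the control, and 5 exceeds the bound of 3 UMIs set before these genes were looked at. Xist (103624 control and 3 RSPO1-Fc UMIs) and the Y-linked Eif2s3y (0 and 3834) and Ddx3y (0 and 2288) also go with a female control and a male RSPO1-Fc source. They had been seen before the test was written. A wrong label on either library was not tested.

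Wnt target genes were lower in the RSPO1-Fc library, opposite to the direction that a Wnt agonist might be thought to give. The non-epithelial cells are argued against as the whole cause, since the median was −1.65 without the named clusters (−1.68 without 65 further control cells that carried immune or non-epithelial genes) and the members shifted by −0.12 (−0.12 to −0.10) where 1.03 was needed. A different mix of epithelial clusters cannot be ruled out: the median among cycling-like cells was −0.96, short of the bound of −1 set after the result was seen, although members shifted by only 0.02 (−0.18 to 0.28). Other numerical kernels gave −1.01 and −0.95, and leaving out 17 of the class's control cells with non-epithelial marker UMIs gave −1.01, so values fall on either side of that bound, and in an earlier run without a fixed kernel this test had passed it. The source of the libraries (animal and segment) and a difference in chemistry cannot be told apart from RSPO1-Fc, because there were 0 further control libraries.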

How the results depend on the processing

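Epithelial clusters only, the same without 2 further clusters led by immune genes, then also without cells non-epithelial by marker UMIs, one UMI limit of 3000, overlapping genes left out, marker UMIs without clustering, the profile of barcodes with over 100 to 500 UMIs, the earlier naming rules and the other numerical kernels were added after seeing the data. Of the list medians, 480 of 526 values stayed within their interval and 26 changed sign. The Wnt target median over all or epithelial cells ranged within −1.68 to −1.18, while it was −0.96 among cycling-like cells. Numbers of 2-fold genes stayed within 1.5 times in 33 of 38 cases, and cells retained in 11 of 12. Non-epithelial shares stayed within their interval in 17 of 22 cases and shares with a UMI in 11 of 40. Of 2650 values for named genes 789 stayed within counting error and 19 changed sign, among them values of Ptgs1, Cdh5, Col4a1, Fabp1, Fabp2, Mki67, Crim1, Pyy and Smad2. Where no cause follows from the setting, it was not tested. No paired analysis was possible because each group has 1 library. Depth limits genes near the floor of 3 counts.

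Under TMM, 1015 genes were higher and 810 lower, and medians were 0.02 (TGF-β components), 0.33 (YAP), 0.24 (Notch), 0.15 (p53), 1.19 (S phase), 1.2 (cholesterol), 0.87 (pan-epithelial), 1.31 (cycling) and 0.33 (fetal). A floor of 100 CPM left 171 and 308 genes (114 and 211 in cycling-like cells), a floor of 5 CPM gave 2414 lower genes. A list floor of 20 CPM gave 0.52 (YAP) and 0.24 (fetal). Epithelial clusters only gave 0.66 (YAP), 0.20 (Notch), −0.09 (Paneth) and 0.36 (fetal), with 0.08 for Ptgs1 and 0.36 for Cdh5. Without 2 further clusters led by immune genes these were 0.65, 0.20, −0.12, 0.36, 0.06 and 0.36, with −3.76 (MHC class II) and −4.77 for S100a9 against −6.61. Without cells non-epithelial by marker UMIs as well, they were 0.75, 0.22, −0.13, 0.36, 0.35 and 0.60, with 0.69 for Col4a1, 0.68 for 1 gene not reported here and −3.53 for Lyz2 against −6.11, and MHC class II genes kept 1 measured member. Thinning to 3000 UMIs gave −0.44 (R-spondin and Wnt receptors), 0.02 (YAP), 1.00 (S phase), −7.56 (MHC class II), 0.66 (pan-epithelial) and −7.35 (fibroblast). Per-cell means gave 0.03 (YAP), 1.04 (S phase), −7.51 (MHC class II), 0.66 (pan-epithelial), 1.28 (cycling) and −7.23 (fibroblast). Totals without mitochondrial and ribosomal protein genes gave 0.06 (YAP) and 0.06 (fetal), and leaving out overlapping genes 0.02 (YAP). A mitochondrial limit of 10% gave −0.03 (Paneth). One UMI limit of 3000 gave −7.17 (MHC class II) and 0.02 (fetal). A pseudocount of 0.1 CPM gave −8.16 (MHC class II), 3.68 (enterocyte), −8.37 (fibroblast), −5.98 (endothelial) and −8.38 (macrophage), and 5 CPM −2.07 (pericyte). Subtraction of the profile of over 100 to 500 UMIs gave −0.94 for Fabp2, −0.06 for Fabp1, −0.27 for Pyy and 0.05 for Mki67. Mki67 was also 0.34 (thinned), 0.23 (TMM) and 0.18 (per-cell means), Crim1 0.61 (epithelial clusters, 0.62 and 0.78 in these 2 settings) and Smad2 0.01 (TMM).

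The 5000 highest barcodes retained 3558 control cells. Naming rule versions 1, 2 and 3 gave non-epithelial shares of 14.5%, 11.3% and 14.5% in the control. The RSPO1-Fc share was 0% without integration and 0% by marker UMIs. With the Sandybridge and Prescott kernels the shares were 16.2% and 16.2% in the control and 0.0745% and 0.0372% in the RSPO1-Fc library. Shares with a UMI at 1500 UMIs and without thinning were, in the control, 8.64% and 45.0% (Lgr5), 7.24% and 27.4% (Mki67), 7.06% and 20.9% (Lyz1), 0.407% and 4.52% (Dclk1), 31.2% and 75.7% (Clu) and 8.96% and 30.3% (Ly6a). In the RSPO1-Fc library they were 2.53% and 21.9% (Lgr5), 10.6% and 59.3% (Mki67), 6.41% and 45.3% (Lyz1), 1.15% and 8.98% (Fabp1), 0.484% and 3.17% (Chga), 55.3% and 99.4% (Clu) and 8.12% and 52.9% (Ly6a). Without thinning, Muc2 was 3.08% and Chga 0.724% in the control, and Muc2 0.782% in the RSPO1-Fc library.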

Other observations

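In epithelial clusters thinned to 3000 UMIs, 4 Wnt targets were compared between cells with and without a UMI of Mki67, Lyz1 or Defa24, genes and splits chosen after seeing the data. By Mki67, intervals lay apart in 4 of 8 comparisons. In the control library, Nkd1 was seen in 67.3% of cells with a Mki67 UMI (142 of 211, 60.5 to 73.6) and 87.0% of cells without one (1427 of 1641, 85.2 to 88.6). Notum, which inactivates Wnt ligands, was seen in 37.0% (30.4 to 43.9) and 50% (47.6 to 52.5), and Axin2 in 46.9% (40.0 to 53.9) and 60.8% (58.4 to 63.2). The intervals of Lgr5 overlapped (12.8%, 8.6 to 18.1, and 18.1%, 16.3 to 20). Control cells with a Mki67 UMI include non-epithelial ones, which lower these shares. Without 65 control cells that carried immune or non-epithelial genes, the shares were 73.4% (66.6 to 79.5) and 88.0% (86.3 to 89.5) for Nkd1, 40.6% (33.6 to 47.9) and 51.0% (48.5 to 53.5) for Notum and 50.5% (43.2 to 57.8) and 61.9% (59.4 to 64.3) for Axin2. In the RSPO1-Fc library the intervals overlapped for Nkd1 (14.8%, 11.8 to 18.1, and 19.4%, 17.8 to 21.2), Notum (9.39%, 7.03 to 12.2, and 12.9%, 11.5 to 14.3) and Lgr5 (2.68% and 4.02%). Their shares were lower with a Mki67 UMI, as in the control, and overlap of intervals does not show that shares are equal. Axin2 was instead seen in 29.9% (26.0 to 34.0) of RSPO1-Fc cells with a Mki67 UMI and 23.1% (21.4 to 25) without. By Lyz1 or Defa24, intervals overlapped in 15 of 16 comparisons. The exception was Nkd1 by Lyz1 in the control, with 71.4% (60 to 81.2) and 85.3% (83.6 to 86.9), and it overlapped too without the 65 cells (80%, 68.2 to 88.9, and 86.6%, 84.9 to 88.2). Only 20 control cells had a Defa24 UMI, which left wide intervals (Nkd1 65.0%, 40.8 to 84.6). In the RSPO1-Fc library 618 cells had one, and how many of these reflect free RNA is unknown. These splits therefore cannot tell whether Wnt targets differ in cells that express Paneth genes. The other 16 of the 20 Wnt targets were not looked at in this way. Cells are not replicates, and whether the libraries differ in this respect was not tested.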
